A study of Mus musculus with 6 samples.

How the data were processed

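The series holds RNA sequencing of cells isolated from mouse brain with magnetic beads that carry an antibody against O4, a sulfatide antigen on the surface of late oligodendrocyte precursors and oligodendrocytes. The labels name the cells oligodendrocytes and state that they were not cultured. Mice of the strain labelled c56Bl/6j were immunised with a peptide of myelin oligodendrocyte glycoprotein (MOG), which induces experimental autoimmune encephalomyelitis (EAE), or were given ovalbumin (OVA), and were killed at the peak of disease. RNA of 6 EAE mice was combined into 3 pools of 2 mice. RNA of 4 OVA mice gave 3 samples, of which 1 combined 2 mice and the others held 1 mouse each. Groups were taken from the treatment label, and replicate numbers follow the order of the deposited samples, so they pair nothing. The 6 samples therefore differ in the number of mice behind each value, and no batch, date or sex is given in the labels.

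Libraries were made with the TruSeq Stranded mRNA kit, which selects polyadenylated RNA and keeps strand, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.17, cutadapt 1.18, STAR 2.6.1c, Subread 1.6.1 and DESeq2 1.24.0, and the mouse build GRCm38, without the role or order of the tools. The deposited table gives 1 value per gene and sample on a log2 scale, and its name and values mark it as the regularised logarithm (rlog) of library-size-scaled read counts made by the authors. The rlog shrinks each gene's values towards the gene's own mean, more strongly for low counts, so a difference between groups is understated for weakly expressed genes. Whether the authors' transformation used the groups, and which gene annotation release was counted, is not given in the sources used here. Each column of the deposited log2 table belonged to 1 of the 6 samples. The table gives no counts, so the depth of each sample is unknown and no counting interval or detection floor can be stated. Of 55298 gene identifiers, 55117 (99.7%) matched a symbol, and positions are those of GENCODE M21 on GRCm38, 1-based. Where several identifiers share a symbol, the symbol stands for the one with the highest mean. Mitochondrially encoded genes were not analysed here, so the list of them fixed beforehand has no result.

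All 25244 genes at exactly 0 in every sample and all others with a mean rlog value under 3 were left out, which left 18161 genes, 15216 of them protein-coding. EAE was compared with OVA by a limma linear model (limma 3.58.1 in R 4.3.3) with empirical Bayes moderation and an intensity trend, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05 on the adjusted p. Every gene-level adjusted p in the text comes from that limma fit unless another setting is named. An error given after a difference is its standard error (SE), and an error given after a group value is the standard deviation (SD) over 3 samples. Folds are 2 to the power of the rlog difference. An exact permutation test of 3 samples against 3 cannot give a two-sided p under 0.1, so every p rests on the spread that limma pools across genes. A pool averages its mice, so the spread between samples is not the spread between single mice.

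Of 40 gene lists fixed before the data were examined, 39 had members among the tested genes. They cover oligodendrocyte stages, myelin lipids, antigen presentation and inflammation, mitochondria and metabolism, stress, death and division, and markers of the other cell types a brain preparation can hold. Each was tested with camera (limma) at a preset correlation of 0.01 between genes, adjusted over the 39 lists, and again with the correlation estimated for each list. Beside each list stand its median difference, the number of members past the gene test, and the number past it when adjusted over the list alone. The genes named in the text follow a rule set beforehand. It takes the 8 largest differences in each direction among genes past the threshold whose groups do not overlap, without predicted gene models. It adds up to 3 members per list past the threshold with the largest difference, plus 1 of opposite direction, or the 2 with the smallest p where none passed. It also names Mbp, Mog, Olig2, Sox10, Pdgfra, Ptprc, Cd74, B2m, Gfap, Aif1 and Cd3e. Another gene that the rule takes is not reported here, and some list members are left out for length.

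The tests were checked on simulated values before the real fit, with 18161 genes given the real means and a spread drawn around the fitted trend. The gene test recovered 24% of 50 genes changed by 0.5 on the log2 scale, 86% at 1, 96% at 2 and 100% at 3, with 9 false calls among all genes (5.56% of the calls). A list of 20 genes shifted by 0.5 passed at an adjusted p of 1.3e-20, and 3 of 100 unshifted lists had p under 0.05. The simulated genes were independent of each other, which real genes of a list are not. Their spread followed the fitted model and was equal in all samples, so the share of false calls need not hold where 1 sample stands apart. No pair of samples shared identical values among the tested genes, and the SD of the difference between a pair ranged from 0.169 to 0.41.

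Each result was recomputed without the filter on low values, with a minimum mean of 5, without the intensity trend, with robust moderation, with median centring or quantile normalisation of the samples, with weights by the number of mice, with array quality weights, and without each sample in turn. A fit on autosomal genes alone was added after the data were seen.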

Results

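The data set compares brain cells captured by the O4 antigen from 3 pools of EAE mice with those from 3 OVA samples. EAE is a model of multiple sclerosis in which immunisation against a myelin protein brings T cells and myeloid cells into the central nervous system. Each value is an rlog value on the log2 scale, so that a difference of 1 stands for a 2-fold difference, shrunk for weakly expressed genes. The depth of the samples is unknown. Among the genes named here the transcript of Mbp, myelin basic protein, was the most abundant, at 17.22 ± 0.35 in OVA (SD, n = 3). The preparations also held transcripts of other brain cells in every sample. In OVA the astrocyte glutamate transporter Slc1a2 stood at 15.55 ± 0.24, the endothelial Vwf at 13.84 ± 0.08 and the leukocyte antigen Ptprc at 11.38 ± 0.34 (SD, n = 3).

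The comparison of EAE with OVA asks which transcripts of O4-captured brain cells differ at the peak of disease. Part of the genes of antigen presentation, of the interferon response and of phagocytes rose in the EAE pools, such as Cd74, Cxcl9 and Ctss, whereas several astrocyte genes and a pair of homeostatic microglia genes fell. Of the genes of myelin and the transcription factors of the oligodendrocyte lineage, limma called 0, with 3 of the former and 4 of the latter at an unadjusted p under 0.05. Apart from Xist, the RNA of the inactive X chromosome, the largest increases among the named genes were those of Arg1, arginase of alternatively activated macrophages, at 29.1-fold, and Gpnmb, a glycoprotein of lipid-laden phagocytes, at 21.2-fold. Decreases were smaller. Among the named genes past the threshold, the largest were those of the Y-linked Ddx3y, Kdm5d and Uty, at 2.72-fold, 2.39-fold and 2.22-fold. Slc4a4, an astrocyte bicarbonate transporter, came next and was 2.20-fold lower in EAE. In total, 312 genes were higher and 121 lower in EAE of 18161 tested, of which 133 were higher and 8 lower by at least 2-fold. The 8 include Ddx3y, Kdm5d and Uty.

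Those counts depended on single samples. The number of higher genes was 84 without EAE replicate 1, 24 without EAE replicate 2, 99 without OVA replicate 1, 30 without OVA replicate 2 and 850 without OVA replicate 3, and that of lower genes was 18, 1, 33, 7 and 346 in the same order and 45 without EAE replicate 3. The count of genes higher by at least 2-fold was 61, 22, 57 and 25 without EAE replicate 1, EAE replicate 2, OVA replicate 1 and OVA replicate 2, and 242 without OVA replicate 3. The count of genes lower by at least 2-fold was 0 without EAE replicate 2, 2 without OVA replicate 1, 2 without OVA replicate 2 and 25 without OVA replicate 3. All 433 genes past the threshold kept their direction whichever sample was left out. Genes chosen for a large difference in these same 6 samples would mostly do so in any case, so this is no separate support. Of 50 named genes past it, 13 stayed past it with every sample left out in turn, namely Xist, Gpnmb, Saa3, Cxcl9, Cd74, Cxcl10, C4b, Ccl5, Slc11a1, Ctss, Cd68, Cd3e and Gfap. The groups did not overlap for 4148 genes, 22.8% of those tested, where chance gives 10% on average over the 10 possible splits of the samples. Because genes vary together, the share of a single split can lie above that average, and the shares of the other splits were not computed.

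Arg1 (ENSMUSG00000019987.9, chromosome 10, 24915221 to 24927484) rose by 4.86 ± 0.53 (SE) on the log2 scale, from 6.26 ± 0.14 in OVA to 11.12 ± 1.23 in EAE (SD, n = 3; limma adjusted p = 0.0085). Gpnmb (ENSMUSG00000029816.10, chromosome 6, 49036546 to 49070929) rose by 4.40 ± 0.22, from 7.66 ± 0.43 to 12.06 ± 0.27 (limma adjusted p = 0.0004). Saa3 (ENSMUSG00000040026.8, chromosome 7, 46711998 to 46715700), an acute phase serum amyloid protein, rose 12.3-fold. Il1rn (ENSMUSG00000026981.15, chromosome 2, 24336853 to 24351494), the interleukin-1 receptor antagonist, rose 11.9-fold, and F10 (ENSMUSG00000031444.16, chromosome 8, 13037308 to 13056676), coagulation factor X, rose 10.6-fold. Their limma adjusted p values were 0.00031, 0.0108 and 0.0118. Arg1, Il1rn and F10 varied among the EAE pools, with Arg1 at 12.436, 10.922 and 10.004 in EAE replicates 1 to 3. Without EAE replicate 2 or without OVA replicate 2, those 3 genes missed the threshold, with adjusted p of at most 0.0703, and F10 also missed it without OVA replicate 1 (0.0516).

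Of 20 genes of MHC class I and the immunoproteasome, which process and display peptides to CD8 T cells, all lay above 0 with a median of 1.12, 9 rose, and 19 did so when adjusted over the list alone. Nlrc5, the transcriptional activator of class I genes, rose 4.09-fold (limma adjusted p = 0.0103), the peptide transporter Tap1 3.53-fold (0.0161), H2-Q7 3.18-fold (0.0118) and the class I light chain B2m 2.52-fold (0.0215). Of 10 MHC class II genes, which display peptides to CD4 T cells, 7 rose, 9 when adjusted over the list alone, and the median was 1.39. Cd74, the class II invariant chain, went from 12.88 ± 0.27 to 14.57 ± 0.17 (SD, n = 3), a rise of 1.69 ± 0.16 on the log2 scale (SE; limma adjusted p = 0.0054). H2-Ab1 and H2-Aa rose 3.36-fold and 3.01-fold. Both lists passed camera (adjusted p = 5.5e-19 and 2.2e-11), but not with an estimated correlation (adjusted p = 0.39 with an estimated correlation for each). OVA replicate 3 lay above the mean of the other OVA samples by a median of 0.63 for class I and 0.47 for class II. The 9 class I genes became 1, 0, 2 and 0 without EAE replicate 1, EAE replicate 2, OVA replicate 1 and OVA replicate 2, and 20 without OVA replicate 3. The 7 class II genes became 1 without EAE replicate 2 and 1 without OVA replicate 2.

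Of 41 interferon-stimulated genes 20 rose and 21 did not pass the test, while 37 rose when adjusted over the list alone. All lay above 0, with a median of 1.16 and a range from 0.31 to 3.56, and the list passed camera with an adjusted p of 7.7e-31, but had an adjusted p of 0.39 with an estimated correlation. Cxcl9 (ENSMUSG00000029417.9, chromosome 5, 92321347 to 92328079), a chemokine induced by interferon gamma that attracts T cells, rose 11.8-fold, from 6.55 ± 0.18 to 10.10 ± 0.39 (SD, n = 3; limma adjusted p = 0.00056). Its neighbour Cxcl10 rose 7.33-fold (0.0045), and Cd274, the checkpoint ligand PD-L1, rose 6.62-fold (0.0115). In OVA replicate 3, 37 of the 41 were higher than in both other OVA samples, by a median of 0.56 over their mean. The 20 genes became 5, 2, 6 and 2 without EAE replicate 1, EAE replicate 2, OVA replicate 1 and OVA replicate 2, and 35 without OVA replicate 3.

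**Figure D1:**
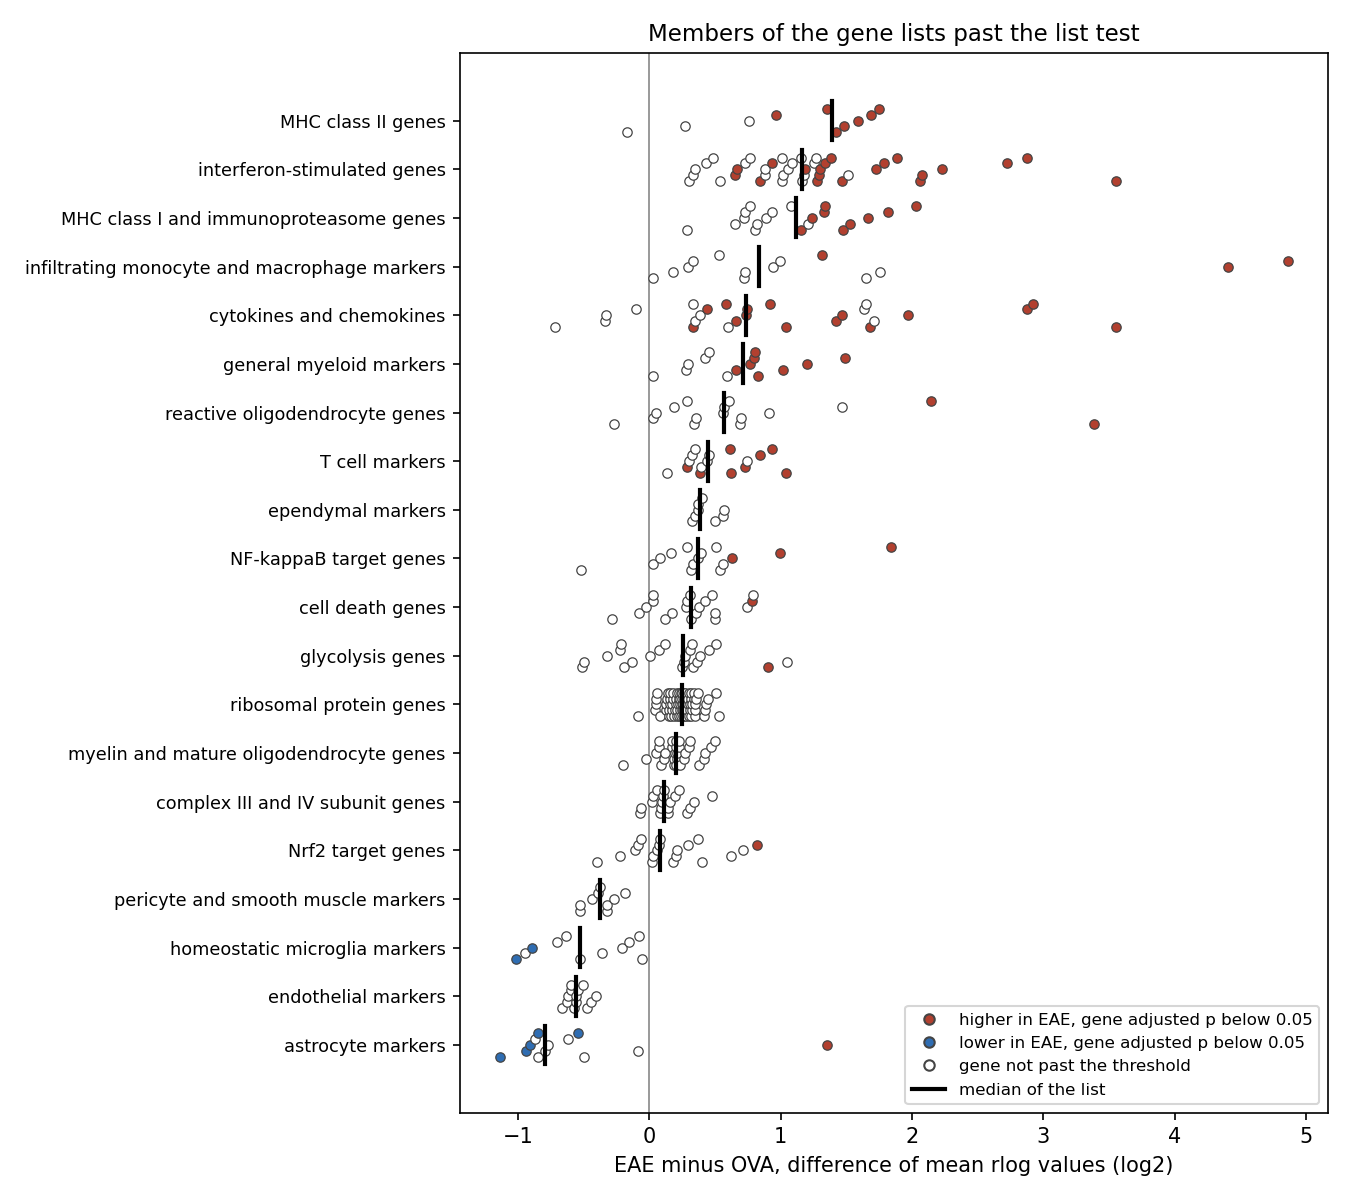
Difference between the mean rlog values of EAE and OVA (log2, horizontal axis) for each member of the 20 lists past camera at a preset correlation, with filled points for genes past the limma threshold and a bar at each list's median. The medians run from -0.79 for astrocyte markers to 1.39 for MHC class II genes, and the ribosomal, myelin, ependymal, endothelial, pericyte and complex III and IV lists hold no gene past the threshold.

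Of 26 cytokines and chemokines 15 rose, 20 when adjusted over the list alone, with a median of 0.74, and 2 others were lower when adjusted over the list alone. Ccl5, which attracts T cells and monocytes, rose 7.59-fold, from 6.46 ± 0.15 to 9.38 ± 0.11 (SD, n = 3; limma adjusted p = 0.00011). The list's camera adjusted p was 2.6e-17, and it was 0.27 with an estimated correlation. Of 15 NF-kappaB targets 3 rose, 9 when adjusted over the list alone with 1 lower, at a median of 0.37 (camera adjusted p = 1.2e-06, and adjusted p = 0.54 with an estimated correlation). They were Tnfaip2 (3.59-fold), Nfkbie (2.00-fold) and the TNF receptor adaptor Traf1 (1.54-fold). The complement and acute phase list did not pass (median 0.12, camera adjusted p = 0.12), although 4 of its 16 members rose, also 4 when adjusted over the list alone beside 3 lower. They were Saa3, the central complement component C3 (6.48-fold, limma adjusted p = 0.0316), C4b (4.43-fold, 0.0053) and, named after its value was seen, complement factor B, Cfb (0.97 on the log2 scale, 0.0335). The 4 became 2 without EAE replicate 1, EAE replicate 2, OVA replicate 1 or OVA replicate 2, and C3 missed the threshold without any of EAE replicates 1 to 3 or OVA replicates 1 and 2 (adjusted p of at most 0.133). The list passed without EAE replicate 3 (adjusted p = 0.0026) and without OVA replicate 3 (0.048). The 15 cytokine genes became 6, 4, 8 and 4 without EAE replicate 1, EAE replicate 2, OVA replicate 1 and OVA replicate 2, and the 3 NF-kappaB targets became 0, 0, 1 and 0 in that order and 6 without OVA replicate 3.

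Of 16 genes known from reactive oligodendrocytes, 15 lay above 0 with a median of 0.57, and 2 rose, 10 when adjusted over the list alone. Serpina3n (ENSMUSG00000021091.8, chromosome 12, 104406729 to 104414329), a protease inhibitor also made by reactive astrocytes, rose 10.5-fold, from 10.18 ± 0.43 to 13.57 ± 0.64 (SD, n = 3; limma adjusted p = 0.0067). The other was the complement gene C4b, at 12.38 ± 0.33 in OVA and 14.53 ± 0.26 in EAE. The list's camera adjusted p was 5.4e-07, and its adjusted p was 0.39 with an estimated correlation. Without EAE replicate 2, Serpina3n had an adjusted p of 0.051, which left 1 gene of the list past the threshold, while 4 passed without EAE replicate 3 and 5 without OVA replicate 3.

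Of 14 general myeloid markers 8 rose, 12 when adjusted over the list alone, at a median of 0.72. Ctss, the lysosomal protease cathepsin S, went from 12.96 ± 0.04 to 14.45 ± 0.13 (SD, n = 3), a 2.82-fold rise (limma adjusted p = 0.00092). Cd68 rose 2.30-fold, the Fc receptor chain Fcer1g 2.02-fold and Aif1 1.58-fold, whereas Ptprc differed by 0.43 (adjusted p = 0.25). Of 14 markers of infiltrating monocytes and macrophages, all lay above 0 with a median of 0.84, and 3 rose, 6 when adjusted over the list alone. The 3 were Arg1, Gpnmb and the endotoxin receptor Cd14 (2.49-fold), of which Gpnmb is also induced in microglia. Of 16 T cell markers 8 rose, 15 when adjusted over the list alone, at a median of 0.45. Their levels were low, with the T cell receptor subunit Cd3e at 4.63 ± 0.04 in OVA and 5.47 ± 0.05 in EAE (SD, n = 3; limma adjusted p = 0.0045), and Icos rose 2.06-fold and Lck 1.91-fold. The rlog shrinks such low values towards each gene's mean. The SDs and adjusted p values of these T cell genes may therefore understate the spread between samples. The 3 lists passed camera (adjusted p = 2.4e-13, 6.0e-08 and 1.9e-16), and none did when the correlation was estimated (adjusted p = 0.26, 0.53 and 0.26 with an estimated correlation). OVA replicate 3 exceeded the other OVA samples for all 14 monocyte markers, by a median of 0.72, and without it 10 of them rose, against 1 without EAE replicate 2 or OVA replicate 2. The 8 myeloid genes became 2 without EAE replicate 1, EAE replicate 2 or OVA replicate 2, and the 8 T cell genes became 5, 1, 4, 4, 1 and 12 without EAE replicates 1 to 3 and OVA replicates 1 to 3 in order.

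Homeostatic microglia markers, which mark resident microglia at rest, lay below 0 for all 11 members with a median of -0.53. P2ry12 (ENSMUSG00000036353.13, chromosome 3, 59216272 to 59262871), the microglial ADP receptor, fell 2.02-fold, from 11.22 ± 0.27 to 10.21 ± 0.30 (SD, n = 3; limma adjusted p = 0.034). Fcrls fell by 0.89 on the log2 scale (0.026). When adjusted over the list alone, 7 were lower. The camera adjusted p was 1.0e-06, and the adjusted p was 0.54 with an estimated correlation. Neither gene passed the threshold without EAE replicate 1, EAE replicate 2, OVA replicate 1 or OVA replicate 2, with adjusted p of at most 0.143, and 4 markers passed it without EAE replicate 3.

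Astrocyte genes moved in opposite directions. Of 13 markers 12 lay below 0 with a median of -0.79, 5 fell and 1 rose, and 11 and 1 did so when adjusted over the list alone. Slc4a4 (ENSMUSG00000060961.15, chromosome 5, 88886818 to 89239653) fell by 1.14 ± 0.15 (SE) on the log2 scale, from 13.19 ± 0.26 to 12.06 ± 0.16 (SD, n = 3; limma adjusted p = 0.0137), and Slc1a2 fell 1.92-fold (0.040). Gfap, the intermediate filament of reactive astrocytes, rose 2.55-fold, from 11.36 ± 0.11 to 12.71 ± 0.19 (0.0045). The list's camera adjusted p was 2.1e-08, and its adjusted p was 0.39 with an estimated correlation. Outside the list, the GABA transporter Slc6a11 (ENSMUSG00000030307.8, chromosome 6, 114131241 to 114249952) fell 2.20-fold, the fatty acid elongase Elovl2 (ENSMUSG00000021364.16, chromosome 13, 41182381 to 41220405) 2.16-fold and the GABA receptor subunit Gabrg1 (ENSMUSG00000001260.10, chromosome 5, 70751047 to 70842617) 2.06-fold. The number of falling markers was 2, 0, 3, 2, 1 and 7 without EAE replicates 1 to 3 and OVA replicates 1 to 3 in order, and Slc4a4 missed the threshold without EAE replicate 2 or OVA replicate 2 (adjusted p = 0.073 and 0.062). Slc1a2 passed with no sample left out other than OVA replicate 3 (adjusted p of at most 0.169), and Slc6a11 and Elovl2 missed the threshold without EAE replicate 2 or OVA replicate 2 and Gabrg1 without EAE replicate 2 (adjusted p of at most 0.082).

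**Figure D2:**
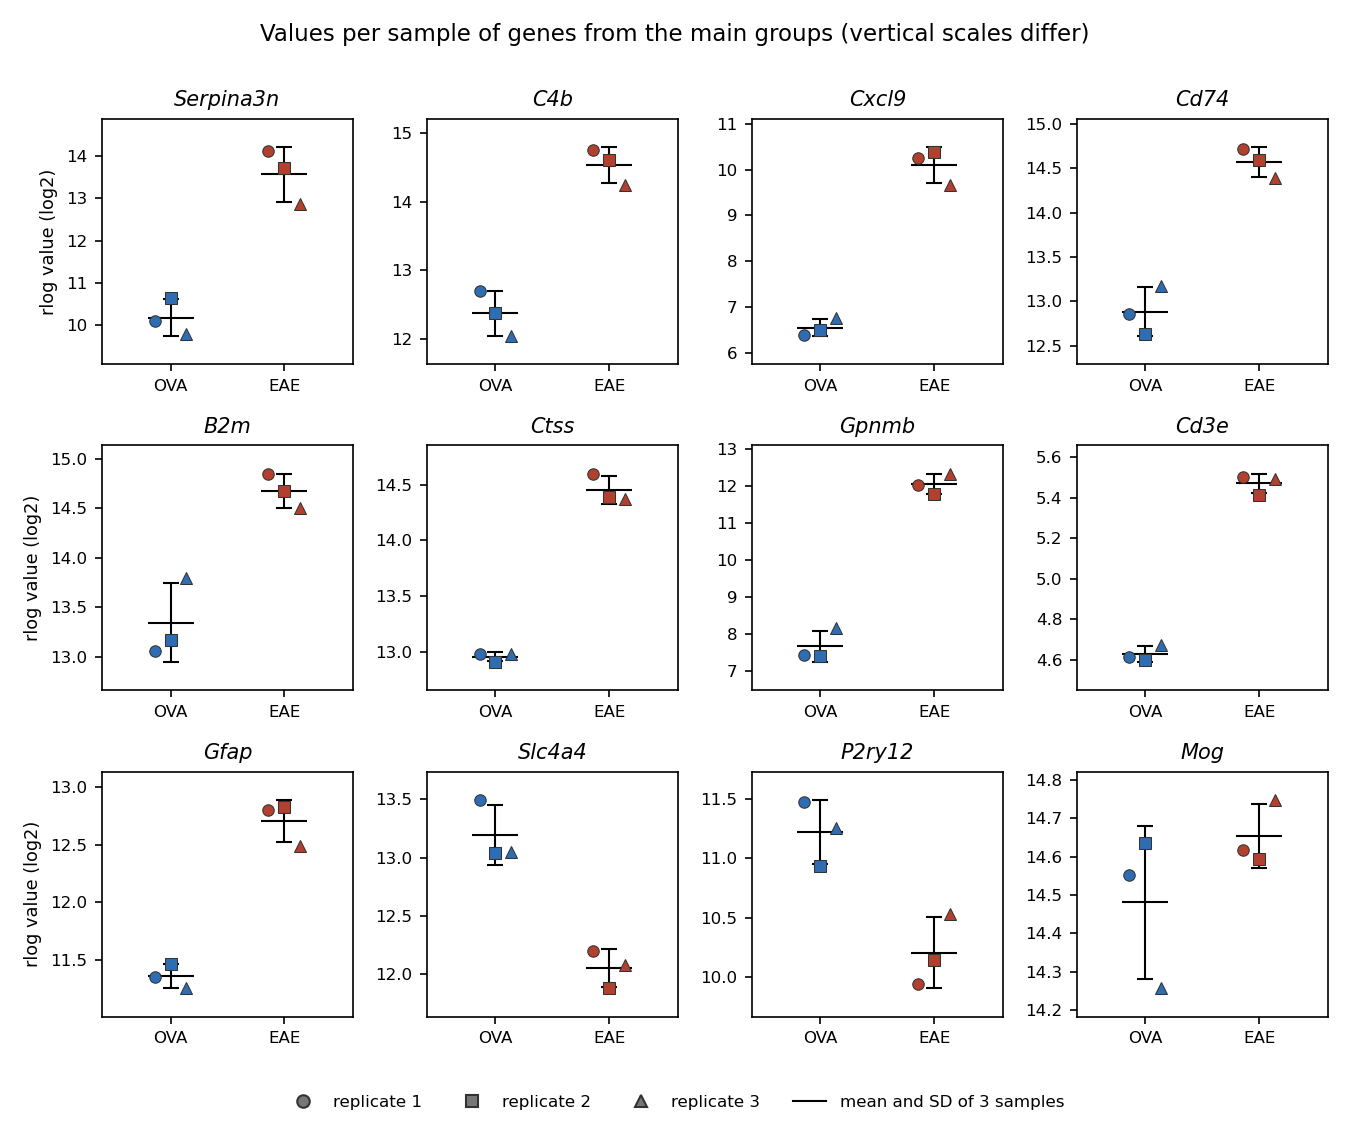
Values of 12 genes per sample (rlog, log2, vertical axis; scales differ between panels) in OVA and EAE, with horizontal lines at the means and bars for the SD of 3 samples. The groups lie apart for every gene shown except Mog, whose means were 14.48 in OVA and 14.65 in EAE.

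Vascular markers lay lower in EAE on average, but the samples of the groups overlapped. In the mean over the list, EAE replicate 2 lay above OVA replicate 1 for endothelial markers (12.34 against 12.19). The same held for pericyte and smooth muscle markers (10.66 against 10.39). All 13 endothelial markers lay below 0 (median -0.56), with 8 at an unadjusted p under 0.05 but 0 past the limma threshold, also 0 when adjusted over the list alone. All 9 pericyte and smooth muscle markers also lay below 0 (median -0.37), with 2 at an unadjusted p under 0.05 and 0 past either threshold. Vwf differed by -0.56 ± 0.16 and the pericyte receptor Pdgfrb by -0.44 ± 0.12 (SE; limma adjusted p = 0.139 and 0.132). The camera adjusted p values were 3.6e-06 and 0.0014, and neither list passed when the correlation was estimated (adjusted p = 0.62 and 0.67 with an estimated correlation). OVA replicate 3 had the highest value of all 6 samples for each of these genes. Without it the medians were -0.33 and -0.18, and the pericyte list missed the threshold (adjusted p = 0.062).

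Genes of mature oligodendrocytes differed by small amounts. Of 30 myelin and mature oligodendrocyte genes 28 lay above 0 with a median of 0.20, but limma called 0, also 0 when adjusted over the list alone, and 3 had an unadjusted p under 0.05. Mbp differed by 0.47 ± 0.25 and Mog by 0.17 ± 0.13 (SE; limma adjusted p = 0.41 and 0.55). The list passed camera (adjusted p = 0.00031), and had an adjusted p of 0.74 with an estimated correlation. It also missed the threshold without OVA replicate 3 (median 0.10, adjusted p = 0.075), a sample whose myelin genes lay below the mean of the other OVA samples with a median of -0.35, and with array quality weights (0.719). Of 17 oligodendrocyte precursor genes 2 fell, Ptprz1 by 0.63 and Tmem100 by 0.50 on the log2 scale (limma adjusted p = 0.0485 and 0.0276), while Pdgfra differed by 0.38 (0.20). Of the 17 members 10 lay above 0 and 7 below, and 3 were lower and 1 higher when adjusted over the list alone. The list did not pass (median 0.28, camera adjusted p = 0.42), and neither Ptprz1 nor Tmem100 passed without EAE replicate 1, 2 or 3 or OVA replicate 1 or 2 (adjusted p of at most 0.20). Ptprz1 also missed the threshold without the filter, without the trend, with robust moderation and with median centring (adjusted p of at most 0.058).

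Newly formed oligodendrocyte genes and lineage transcription factors did not pass camera either (medians 0.10 and 0.19, adjusted p = 0.24 and 0.28). Limma called 0 of their 16 and 15 members, with 3 of the former and 4 of the latter at an unadjusted p under 0.05. Adjusted over the list alone the counts were 1 and 0, and the 1 was Kif19a, a kinesin, at 0.46 ± 0.10 (SE; limma adjusted p = 0.0697). Sox10 differed by 0.37 ± 0.16 and Olig2 by 0.28 ± 0.20 (SE; limma adjusted p = 0.31 and 0.51). Cholesterol synthesis genes had a median of 0, a mean of -0.009 and a camera direction below 0 (adjusted p = 0.92), with 0 of 22 called by limma over all genes or adjusted over the list alone and 3 at an unadjusted p under 0.05. The list passed without OVA replicate 1 (median 0.09, adjusted p = 0.043). Genes of fatty acid and sphingolipid synthesis had a median of 0.051 and a mean of 0.008 but a camera direction below 0 (adjusted p = 0.85), with 0 of 20 called and 1 lower when adjusted over the list alone. That 1 was Fads2, a fatty acid desaturase, at -0.35 ± 0.07 (SE; limma adjusted p = 0.055), and 2 genes had an unadjusted p under 0.05. Their median was -0.007 after quantile normalisation, -0.019 without EAE replicate 3 and -0.053 without OVA replicate 3.

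Nuclear genes of the respiratory chain differed by small amounts. Of 19 subunits of complexes III and IV 17 lay above 0 with a median of 0.11 (camera adjusted p = 0.0092, and adjusted p = 0.78 with an estimated correlation), with 0 called by limma over all genes or over the list alone and 3 at an unadjusted p under 0.05. Cox8a differed by 0.48 ± 0.13 (SE; limma adjusted p = 0.12). Without OVA replicate 1 the median was -0.001 and the list did not pass (adjusted p = 0.554), nor did it with array quality weights (0.0562). The 36 complex I and 15 ATP synthase genes had medians of 0.06 and 0.03 (camera adjusted p = 0.11 and 0.35), 0 genes past the threshold by either adjustment, and 2 each at an unadjusted p under 0.05. Both lists passed without OVA replicate 3 (adjusted p = 0.017 for each), where 1 complex I gene rose, and complex I also without OVA replicate 2 (0.034), while their medians were -0.009 and -0.068 without OVA replicate 1. The 22 citric acid cycle genes had a median of -0.06 (camera adjusted p = 0.16), and limma called 0, with 0 at an unadjusted p under 0.05. They passed without OVA replicate 1 (0.0072).

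In metabolism and redox defence, few genes rose. Of 22 glycolysis genes 1 rose, whereas 3 rose and 1 fell when OVA replicate 3 was left out. The 1 was Hk2, the inducible hexokinase, which rose by 0.90 ± 0.16 on the log2 scale (SE; limma adjusted p = 0.035), and 8 were higher and 3 lower when adjusted over the list alone. The list's median was 0.26 (camera adjusted p = 0.044, and adjusted p = 0.74 with an estimated correlation). It did not pass without EAE replicate 1 (0.16), EAE replicate 2 (0.052), OVA replicate 1 (0.10) or OVA replicate 2 (0.10). Of 19 Nrf2 targets 1 rose, also 1 when adjusted over the list alone, at a median of 0.08 (camera adjusted p = 0.023, and adjusted p = 0.62 with an estimated correlation). It was Ftl1, the ferritin light chain, which rose 1.77-fold (limma adjusted p = 0.031). The Nrf2 list did not pass without EAE replicate 1 (0.11), OVA replicate 1 (0.12) or OVA replicate 2 (0.054), and without any of those or EAE replicate 2 neither Hk2 nor Ftl1 passed (adjusted p of at most 0.14). Among 17 iron handling genes the phagosomal metal transporter Slc11a1 rose 1.98-fold (0.0054), Ftl1 rose, and the copper-dependent ferroxidase Heph fell by 0.60 on the log2 scale (0.027). Heph missed the threshold without any of EAE replicates 1 to 3 or OVA replicates 1 and 2 (adjusted p of at most 0.136). Adjusted over the list alone, 3 were higher and 2 lower. That list did not pass, and its median of -0.086, mean of 0.003 and upward camera direction differed in sign (adjusted p = 0.98). Thioredoxin and glutathione genes had a median of 0.03, with 0 of 29 called over all genes or over the list alone, 6 at an unadjusted p under 0.05 and a camera adjusted p of 0.47. They passed without OVA replicate 3 (0.048), where 4 rose and 1 fell, and the median of thioredoxin and glutathione system genes was -0.032 without OVA replicate 1.

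In 5 lists of stress and growth, limma called 1 gene each for cell death and immediate early genes and 0 for the others. The 76 ribosomal protein genes lay above 0 for 75 members (median 0.25, camera adjusted p = 2.3e-13, and adjusted p = 0.66 with an estimated correlation), with 0 called by limma over all genes or over the list alone and 24 at an unadjusted p under 0.05. OVA replicate 3 exceeded both other OVA samples for 74 of them, and without it 20 rose. Of 20 cell death genes Tnfrsf1b, which encodes 1 of the TNF receptors, rose 1.72-fold (limma adjusted p = 0.032). Tnfrsf1a, which encodes another, differed by 0.025 (limma adjusted p = 0.96). Adjusted over the list alone, 9 cell death genes rose. The list passed camera at a median of 0.32 (adjusted p = 5.2e-05, and adjusted p = 0.62 with an estimated correlation). In this list 7 genes rose without OVA replicate 3 and 2 without EAE replicate 3. Of 19 immediate early and dissociation stress genes Egr2 rose 2.55-fold (0.0057), and 3 were higher and 3 lower when adjusted over the list alone (median 0.09, camera adjusted p = 0.58). The 25 genes of the unfolded protein and integrated stress responses had 0 called over all genes or over the list alone, 5 at an unadjusted p under 0.05, a median of 0.12 and a camera adjusted p of 0.097. They passed without EAE replicate 3 (0.029) and without OVA replicate 2 (0.0025). Tnfrsf1b missed the threshold without EAE replicate 1 or 2 or OVA replicate 1 or 2, and Egr2 without EAE replicate 2 or OVA replicate 2 (adjusted p of at most 0.14 and 0.051). Cell division genes had a median of -0.018, a mean of 0.02 and an upward camera direction (adjusted p = 0.93), and limma called 0 of 30, with 0 at an unadjusted p under 0.05. Without OVA replicate 3 their median was 0.27 (camera adjusted p = 2.0e-10) and 4 rose.

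Markers of further cell types mostly had no gene past the threshold. All 8 ependymal markers lay above 0 (median 0.39, camera adjusted p = 2.6e-05, and adjusted p = 0.54 with an estimated correlation), with 0 called by limma, 6 at an unadjusted p under 0.05 and 6 higher when adjusted over the list alone. Foxj1, the regulator of motile cilia, differed by 0.57 ± 0.12 (SE; limma adjusted p = 0.062), and without OVA replicate 3, 6 of the 8 rose. Neutrophil markers (median -1.02, camera adjusted p = 0.098), erythroid markers (median -0.46, 0.12) and B cell and plasma cell markers (median -0.22, 0.47) had 0 called of 11, 7 and 11. At an unadjusted p under 0.05 there were 2, 0 and 1, and over the list alone 0, 0 and 1, which was Cd22. OVA replicate 3 lay above the mean of the other OVA samples by a median of 2.59, 1.31 and 1.38 for these 3 lists. With that sample left out their medians were -0.125, -0.022 and 0.125, and none passed (camera adjusted p = 0.61, 0.77 and 0.15). The neutrophil list passed without the filter, without OVA replicate 1 and without OVA replicate 2 (adjusted p = 0.038, 0.0072 and 0.022), and the erythroid list without EAE replicate 3 and without OVA replicate 2 (0.017 and 0.013). Neuron markers (median 0.09, camera adjusted p = 0.23) and fibroblast markers (median -0.06, 0.59) had 0 called of 13 and 7, with 2 and 0 at an unadjusted p under 0.05 and 0 when adjusted over the list alone. The neuron list passed without EAE replicate 1 (0.0055).

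Sex-linked transcripts differed between the groups. Xist (ENSMUSG00000086503.4, chromosome X, 103460366 to 103483254), the non-coding RNA of the inactive X chromosome, rose by 6.19 ± 0.17 (SE) on the log2 scale, from 7.55 ± 0.14 in OVA to 13.74 ± 0.36 in EAE (SD, n = 3; limma adjusted p = 2.0e-05). The Y-linked genes Ddx3y (ENSMUSG00000069045.11, chromosome Y, 1260771 to 1286629), Kdm5d (ENSMUSG00000056673.14, chromosome Y, 897788 to 956786) and Uty (ENSMUSG00000068457.14, chromosome Y, 1096861 to 1245759) fell 2.72-fold, 2.39-fold and 2.22-fold (limma adjusted p = 0.0153, 0.0307 and 0.0142). All 3 missed the threshold without EAE replicate 2, OVA replicate 1 or OVA replicate 2, and Kdm5d also without EAE replicate 1 (adjusted p of at most 0.121). Of the genes past the threshold, 5 lower genes lay on Y, 5 lower and 4 higher genes on X. The labels give no sex, and every difference above was measured between groups that also differ in these transcripts. Among autosomal genes alone, a fit added after the data were seen, 308 genes were higher and 111 lower, and 5 fell by at least 2-fold. By camera at the preset correlation, 15 lists were higher in that fit, against 16 over all genes, and 4 were lower in each.

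**Figure D3:**
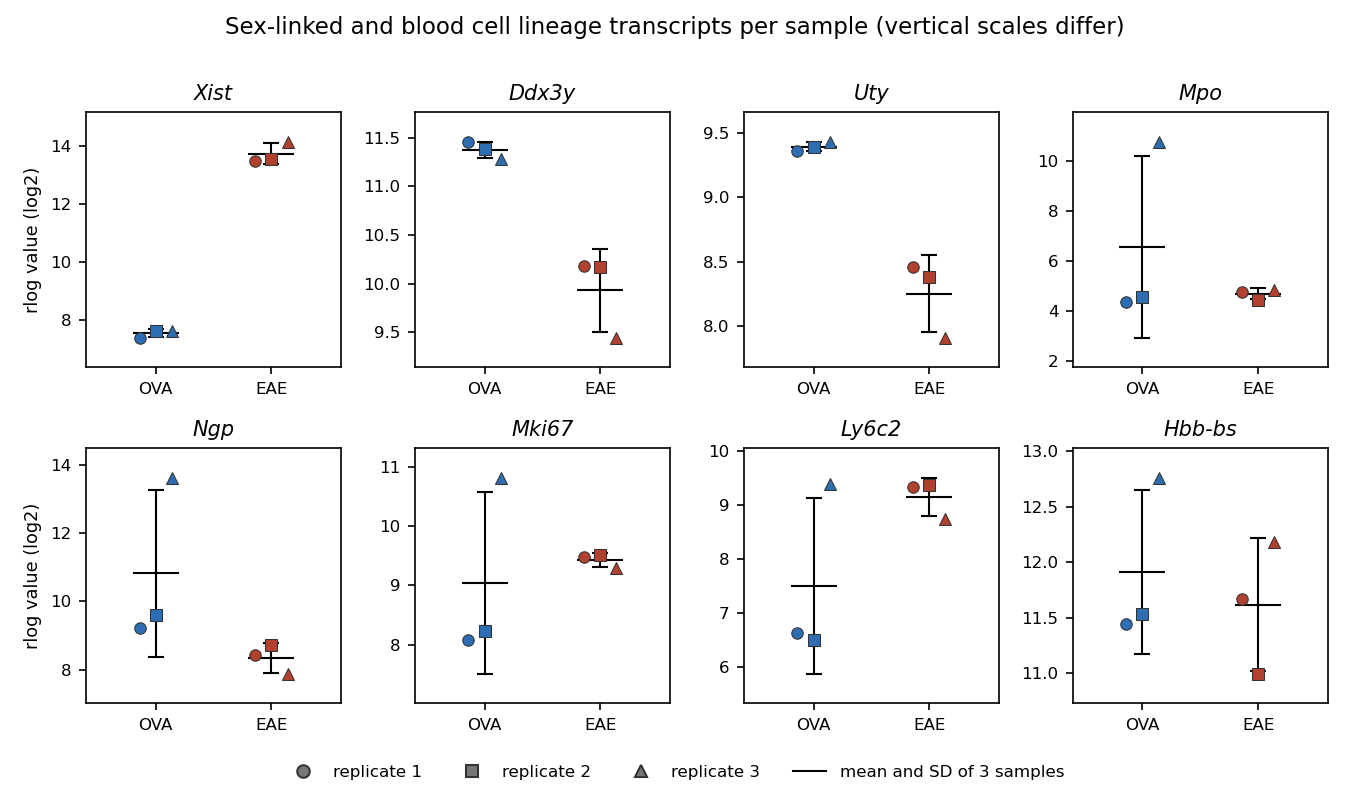
Values of 8 genes per sample (rlog, log2, vertical axis; scales differ between panels), with means and the SD of 3 samples. Xist lay between 13.51 and 14.16 in the EAE pools and between 7.39 and 7.63 in the OVA samples, and Mpo, chosen after its values were seen, stood at 10.8 in OVA replicate 3 against 4.36 and 4.58 in the other OVA samples.

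The first principal component held 50.1% of the variance and separated the groups. The second held 31.9% and put OVA replicate 3, at -31.7, and OVA replicate 1, at 20.3, at opposite ends. The other samples lay between -3.95 and 6.03. Over all lists 16 were higher and 4 lower by camera at the preset correlation, and 0 passed with estimated correlations, where 3 had an unadjusted p under 0.05 and the lowest adjusted p was 0.26. The list calls therefore rest on taking the genes of a list as nearly uncorrelated.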

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

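The fit on autosomal genes alone was chosen after the data were seen. All 433 genes past the threshold kept their direction under every alternative in which they were tested, which is no separate support, since the same samples chose them. Changes of the filter, trend, moderation or scaling, and weights by the number of mice, gave 261 to 441 higher and 102 to 172 lower genes. With array quality weights 2858 genes were higher and 2233 lower, and 283 were higher by at least 2-fold. Those weights were 8.85 for OVA replicate 2 but 0.275 and 0.222 for OVA replicates 1 and 3, and their estimate stopped before it reached its convergence tolerance. Among autosomal genes 5 were lower by at least 2-fold, since the fit left out Ddx3y, Kdm5d and Uty. With each sample left out in turn, 24 to 850 genes were higher and 1 to 346 lower, and 22 to 242 were higher and 0 to 25 lower by at least 2-fold. Each such fit has fewer samples, and the cause of the spread between them was not tested. With the correlation estimated for each list, 0 lists were higher and 0 lower, where 3 had an unadjusted p under 0.05.

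Directions reversed for values that had not passed the test, apart from the list of complexes III and IV. With array quality weights the difference was 0.06 for Col1a1 and -0.007 for Olig2. The list medians under those weights were -0.01 for fatty acid and sphingolipid synthesis, -0.002 for ATP synthase, -0.026 for the unfolded protein response, 0.297 for cell division, 0.074 for B cell and 0.06 for fibroblast markers. The fatty acid median was -0.007 after quantile normalisation and the cell division median 0.054 with weights by mice. With each sample left out in turn, the median of fatty acid and sphingolipid synthesis genes ranged from -0.053 (without OVA replicate 3) to 0.076, that of cell division genes from -0.142 to 0.274, that of B cell and plasma cell markers from -0.463 to 0.125, and that of fibroblast markers from -0.226 to 0.131, the last 3 with their highest value without OVA replicate 3. The value opposite to the others came without OVA replicate 1 for 6 lists. The median of complex I subunit genes ranged from -0.009 to 0.092 and that of complex III and IV subunit genes from -0.001 to 0.193. The median of ATP synthase subunit genes ranged from -0.068 to 0.111, and the median of thioredoxin and glutathione system genes from -0.032 to 0.053. The median of iron handling genes ranged from -0.126 to 0.015, and that of immediate early and dissociation stress genes from -0.015 to 0.158. Over all alternatives, list medians kept direction and side of the threshold in 499 comparisons, gained it in 16, lost it in 11 and reversed in 20. Named genes did so in 1189, 54, 126 and 2. The cause was not tested, and the unknown depth leaves open how far counting error limits the low genes.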

Other observations

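The gene lists and tests below were chosen after the result was seen, apart from the counts over other splits of the samples. The 3 lists named here were written after their members' values were seen, so no test of a list as a whole is given for them. Of 22 genes of the disease-associated state of microglia, which phagocytes take on near damaged myelin, 11 rose in the test over all genes. Clec7a rose 8.13-fold (limma adjusted p = 0.0098), Cst7 6.07-fold (0.000456), Spp1 5.51-fold (0.0302) and Itgax 3.87-fold (0.0118), whereas Trem2 and Apoe differed by 0.29 and 0.28 (0.40 and 0.38). Of 39 lysosomal genes 10 rose. Ctsz rose 2.20-fold, Grn, the progranulin gene, 1.82-fold and Ctsd 1.77-fold (0.0053, 0.0054 and 0.0201). Of 38 genes of the axoneme of motile cilia 37 lay above 0 and 4 rose, which were Dnaaf3, Cfap65, Dnah3 and Dnah2, by 0.54, 0.52, 0.39 and 0.36 on the log2 scale (limma adjusted p = 0.0233, 0.0237, 0.0474 and 0.0354). The 8 markers of ependymal cells, which carry such cilia, had a median of 0.39 with 0 called by limma and 6 at an unadjusted p under 0.05, and 6 rose without OVA replicate 3.

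The following genes were named after their values were seen and stand for no wider group. Nos2, the inducible nitric oxide synthase, rose 7.25-fold and Acod1, which makes itaconate, 5.62-fold (limma adjusted p = 0.0394 and 0.0215). Ifng, Il17a and Foxp3, the transcription factor of regulatory T cells, rose from low levels, with Ifng at 3.93 ± 0.06 in OVA and 4.37 ± 0.10 in EAE, Il17a at 3.35 ± 0.003 and 3.69 ± 0.06, and Foxp3 at 3.73 ± 0.01 and 4.16 ± 0.05 (SD, n = 3; limma adjusted p = 0.0246, 0.0207 and 0.0115). The rlog shrinks such low values towards each gene's mean, so the samples of a group lie close together, as with Il17a at 3.35, 3.355 and 3.355 in OVA. These SDs, and the adjusted p values that rest on them, may therefore understate the spread between samples. Among receptors of astrocytes, Ednrb fell 1.96-fold, Gabrb1 1.89-fold and Egfr 1.86-fold (limma adjusted p = 0.0115, 0.0246 and 0.0081).

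Xist was higher and Y-linked genes were lower in every EAE pool than in every OVA sample. The median of 4 Y-linked genes was 52.0%, 45.4% and 27.7% of the OVA mean in EAE replicates 1 to 3, 41.7% on average, which is consistent with pools that hold RNA of female and male mice. An effect of sex on the other differences cannot be told apart from that of immunisation, because 0 samples had a Xist level that went against their group.

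For the genes of antigen presentation, the interferon response and the myeloid and T cell lists that rose in the EAE pools, 3 explanations were weighed. A larger share of microglia in the state seen in OVA was argued against by the homeostatic microglia markers, with a median of -0.53 and no member above 0. Infiltrating T cells and monocytes remain a candidate explanation. Of 16 T cell markers 15 were higher in every EAE pool than in every OVA sample. Their values were low and shrunk by the rlog, with list means of 5.08 to 5.24 in OVA and 5.63 to 5.72 in EAE. Of 14 monocyte markers 13 lay above OVA replicates 1 and 2 in every EAE pool, but 6 lay above all OVA samples. Selection by O4 would be meant to remove T cells and monocytes. Microglia also make Gpnmb, Cd14 and Lyz2 of the monocyte list, and Lyz2 stood at 14.60 ± 0.20 in EAE and 12.84 ± 0.96 in OVA (SD, n = 3). Expression by the oligodendrocytes themselves, with a median of 0.57 over the reactive oligodendrocyte genes, cannot be told apart from that of other cells, since astrocytes also make Serpina3n and C4b.

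OVA replicate 3 stood apart in transcripts of blood cell precursors, and it also had the highest value of all 6 samples for 13 of 13 endothelial, 9 of 9 pericyte and 7 of 7 fibroblast markers. Mpo, of neutrophil precursors, lay 80.0-fold above the mean of the other OVA samples, and Camp, Ngp, Elane and Rag1 lay above it by 4.46, 4.21, 2.80 and 2.21 on the log2 scale. The haemoglobin genes lay 2.41-fold to 2.50-fold above that mean, and Mpo exceeded their highest difference by 5.00 on the log2 scale. Circulating blood alone cannot be told apart from other sources by this comparison. The high level of haemoglobin genes in the other OVA samples (Hbb-bs at 11.44 and 11.54, Mpo at 4.36 and 4.58) makes an added share appear as a smaller fold. Bone marrow cells in the sample may account for the blood cell transcripts. There, 29 of 30 cell division genes were higher than in both other OVA samples, by a median of 1.01 over their mean. That count alone does not single out marrow. Of the ribosomal protein genes 74 of 76 were higher there too, and of the class I genes 20 of 20, by medians of 0.35 and 0.63. The source of the vascular and fibroblast transcripts was not tested. The design gives no condition that sets this sample apart, so no explanation by a condition of the mouse was tested.

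The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 433 genes, and the highest of the others 0, with 175 to 1448 genes at an unadjusted p under 0.05 in limma against 2963 for the real split, so that 1 of 10 splits gave as many. For lists the real split gave 20 and the highest of the others 32, and 6 of 10 gave as many. The split with 32 lists put OVA replicate 3 together with EAE replicates 1 and 2.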
